A study of Homo sapiens with 9 samples.

How the data were processed

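Total RNA (6 µg per sample) from MOLT4 cells, an established line of human T cell acute lymphoblastic leukaemia, was measured on Affymetrix oligonucleotide arrays with 22283 probe sets. Of the 9 arrays, 3 held parental cells (Control), 3 held a subline selected on 7-hydroxymethotrexate (7-OHMTX) at a final 30000 nM, and 3 held a subline selected on methotrexate (MTX) at a final 300 nM. Groups and replicate numbers were taken from the sample titles. The description of all 9 samples calls the cells untreated, while the treatment notes give the selection and at least 3 passages without drug before harvest. The 7-OHMTX group is named by its label throughout, since RNA of another cell line or a wrong label stays open for it.

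The deposited values are MAS5 signal intensities on a linear scale, made by the authors with Affymetrix software whose version is not given in the sources used here. MAS5 scales each array so that its trimmed mean, without the lowest and highest 2% of values, equals a target. The trimmed mean was 500.2 on the Control arrays and 100.0 on the 6 others, a ratio of 5.00, so the target differed by group. Deposited medians were 143, 161 and 141 for Control replicates 1, 2 and 3, then 27.6, 30 and 29 for 7-OHMTX, and 29.4, 29.2 and 30.9 for MTX. No detection calls were used. For arrays, their number limits the precision.

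Each array was rescaled to a trimmed mean of 100, 16 was added, log2 was taken, and the arrays were quantile normalized. Quantile normalization had been set as the main choice in case the trimmed means differed by more than 5%. Adding 16 damps noise near the background and understates the change of genes with low signal. Gene signals in the text are means ± SD of the normalized values turned back to the linear scale without the added 16, those of control probe sets are rescaled only, and log2 changes are on the scale of the normalized signal + 16. A probe set was tested if it lay above the median of its array in at least 3 of the 9 arrays, and 68 control probe sets were left out, which left 12297. Of all probe sets, 19071 carried 1 gene symbol, 1043 carried several and 2169 carried none. Symbols of 19059 were looked up by Entrez identifier, which changed 0 of them. The 10882 tested probe sets with 1 symbol covered 7448 genes, and a gene was represented by its probe set with the highest mean.

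All 9 arrays were fitted together with limma 3.58.1 on R 4.3.3, with 1 mean per group and an intensity trend in the moderated variance (6 residual and 8.06 prior degrees of freedom). The moderated F test compared the 3 groups, and 3 contrasts compared them in pairs, each with Benjamini-Hochberg adjustment over all tested probe sets at 0.05 and with 95% confidence intervals. The labels call the replicates biological and describe 1 selection per drug, so the p-values measure the spread between these arrays only. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over 35 lists with at least 5 measured genes. Values of single arrays, such as the ratio of 3' to 5' probe sets, were compared by exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.

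The groups, contrasts, thresholds, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule takes the 10 largest rises and the 10 largest falls of each contrast among genes with an adjusted p under 0.05 and no overlap between the groups' arrays. It adds FPGS, SLC19A1, TYMS and GGH, each folate gene past the threshold, and up to 4 members with the largest change from each list described. In the present text 1 of the 5 genes to be named in every contrast is not analysed, and XIST and Y-linked genes are not named.

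Alternatives covered other scalings (median centring, the deposited values, a trimmed mean of 500, and no quantile normalization), other added constants, other filters, the mean of a gene's probe sets, array weights, the ordinary test without moderation, a replicate block, only the groups compared, and leaving out each array in turn. A common trimmed mean without quantile normalization, and one of 500 with it, were chosen after seeing the data. The pipeline was tested on simulated data with 200 changed genes. For 7-OHMTX against Control it called 19.4%, 65.7% and 97.0% of genes changed by a log2 of 0.5, 1 and 2, with 5.97% false calls. For MTX against Control it called 19.4%, 65.7% and 92.4%, with 5.34% false calls. A simulated list of 30 genes shifted by 0.5 was called in both, and 0 of the other lists were called by camera. The simulated noise was independent between probe sets, so this does not test false calls of lists whose genes vary together. Far more probe sets changed in the real data, so these rates need not hold there.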

Results

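Gene expression was measured in the human T cell leukaemia line MOLT4, in a subline selected on the antifolate methotrexate (MTX), and in a subline selected on 7-hydroxymethotrexate (7-OHMTX), a metabolite of MTX that carries an added hydroxyl group. The series asks which genes go with resistance to each drug. It also names loss of the activity of FPGS, the enzyme that adds glutamates to folates and antifolates. The parental cells (Control) and each subline were represented by 3 arrays, and this number limits the precision. Final drug concentrations were 30000 nM for 7-OHMTX and 300 nM for MTX, so the doses differ, and all cells had at least 3 passages without drug before harvest.

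Arrays of each group resembled one another more than those of other groups. Across the 12297 tested probe sets, which are not independent replicates, Pearson's r between arrays was 0.982 to 0.988 within Control, 0.970 to 0.979 within 7-OHMTX and 0.955 to 0.980 within MTX. Control and MTX arrays correlated at 0.900 to 0.943. The arrays labelled 7-OHMTX correlated less with Control (0.850 to 0.869) and with MTX (0.836 to 0.879). In the moderated F test, 7560 probe sets (61.5%) differed among the 3 groups. The ratio of the 3' to the 5' probe set of ACTB, a sign of RNA integrity and labelling, was 0.971 ± 0.0386 in Control, 1.19 ± 0.0529 in 7-OHMTX and 1.18 ± 0.00575 in MTX (SD, n = 3). For Control against the 6 other arrays, the exact two-sided permutation p was 0.0119, the smallest of 84 arrangements, and 0.178 after adjustment over 16 tests. Comparisons of 3 with 3 arrays cannot go below an exact p of 0.1. The same ratio for GAPDH was 0.906, 0.931 and 0.914 in the 3 groups (exact p = 0.619 for Control against the others). The spiked-in cre control was at 2036 ± 204 in Control, 2902 ± 368 in 7-OHMTX and 3197 ± 697 in MTX (exact p = 0.0238 for Control against the others). The 3' probe set for 18S ribosomal RNA was at 363 ± 300, 1745 ± 878 and 1780 ± 938 (exact p = 0.0357). Both had an adjusted exact p of 0.178.

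The comparison of the arrays labelled 7-OHMTX with Control asked what differs in the subline selected on the metabolite. LGALS1, galectin-1, a carbohydrate-binding protein, rose from 2.15 ± 0.28 to 687 ± 47.2 (SD, n = 3). IL32, a cytokine, rose from 1.79 ± 0.11 to 649 ± 203, and SOSTDC1, a secreted antagonist of BMP and Wnt signalling, from 2.38 ± 0.64 to 651 ± 130. BEX3 fell from 1693 ± 238 to 11.1 ± 6.23. EPB41L2, a membrane-cytoskeleton linker, fell from 431 ± 68.0 to 1.64 ± 0.91, and OAT, a mitochondrial aminotransferase of ornithine, from 307 ± 53.7 to 1.95 ± 0.16. The lower mean of each of these genes was under the 16 added to the signal, so their order by fold depends on that constant.

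The other named rises were in VAMP8, TENT5A, CYTL1, IFITM3, SSX1, IFITM2 and CRIP1, with log2 changes of 3.76 to 4.45. HEBP2, ABCG1, BEX1, CERS6, TCEAL9 and the thymocyte chemokine receptor CCR9 had log2 changes of -4.55 to -4.06. CCR9 fell from 579 ± 17.1 to 14.5 ± 6.44. The adjusted p was 5.82e-09 or lower for each of these genes. Outside the X and Y chromosomes, 49 genes had a signal of at least 100 in all 3 arrays labelled 7-OHMTX and under 20 in the 6 others, or the reverse, compared with 2 for MTX and 0 for Control. RNA of another cell line or a wrong label therefore stays open for the arrays labelled 7-OHMTX, and no genotype was used to test it.

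Genes of the T cell receptor and T lineage fell as a group in the arrays labelled 7-OHMTX. Of 39 measured genes, 26 fell, 4 rose and 9 did not pass, and adjusted over the list alone 27 fell and 4 rose. Among all 7448 tested genes 1758 fell and 1582 rose. The median log2 change was -1.01 (camera, adjusted p = 3.07e-08; adjusted p = 0.0326 with an estimated correlation). Besides CCR9, members of the CD1 family fell. CD1C fell from 211 ± 10.4 to 2.82 ± 0.60, CD1D from 199 ± 22.3 to 4.8 ± 3.49 and CD1E from 163 ± 20.2 to 3.84 ± 3.21. Among 35 lists this was the only one called by camera at the preset correlation and with quantile normalization. Cytosolic ribosomal proteins, with 14 up and 5 down of 50 (adjusted p = 0.302), were called higher with median centring (adjusted p = 6.92e-06) and without quantile normalization (adjusted p = 1.78e-06). Oxidative phosphorylation, with 16 up and 2 down of 53 (adjusted p = 0.241), was called higher without quantile normalization (adjusted p = 0.0391). The list of serine synthesis and the amino acid stress response, with 12 genes up and 3 down of 29 (adjusted p = 0.182), passed without 7-OHMTX replicate 3 (adjusted p = 0.0219) or without Control replicate 2 (adjusted p = 0.0457). For actin cytoskeleton and adhesion, not called, the median was -0.16, the mean 0.10 and the test's direction lower. Markers of other cell types were mixed. Of 9 B cell genes 3 rose and 3 fell (adjusted p = 0.88), and of 5 natural killer genes 2 rose and 1 fell (adjusted p = 0.686). With the values as deposited both lists were called higher than other genes (adjusted p = 1.49e-07 and 0.00581). That setting keeps Control values on a scale 5 times larger, so the added 16 ranks genes of low signal higher even without a change. Those calls therefore cannot decide whether the lists rose. Fry called both lists as well (adjusted p = 0.000736 and 0.00121). The myeloid (1 up and 0 down of 6), erythroid (0 and 0 of 5) and epithelial or fibroblast genes (1 and 2 of 8) each had an adjusted p of 0.941.

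Folate genes moved in both directions between the arrays labelled 7-OHMTX and Control. Of 24 tested genes, 9 rose and 7 fell, and adjusted over the list alone 16 changed. FPGS fell from 154 ± 26.1 to 94.8 ± 9.32 (log2 change -0.61 ± 0.17 SE, adjusted p = 0.00954). Without Control replicate 3 it changed by -0.49 (adjusted p = 0.057). GGH, which removes the glutamates that FPGS adds, rose from 220 ± 19.6 to 641 ± 146 (1.46 ± 0.18, adjusted p = 1.54e-05). TYMS, thymidylate synthase, fell from 3071 ± 57.2 to 1869 ± 277 (-0.72 ± 0.11, adjusted p = 0.000171). SLC19A1, the reduced folate carrier, was at 192 ± 19.5 and 191 ± 17.3 in its probe set with the highest mean (-0.01 ± 0.14, adjusted p = 0.969). The probe sets of this gene disagreed, since another fell by 1.36 (adjusted p = 7.13e-05) and a further one changed by -0.19 (adjusted p = 0.454). The mean of all its probe sets passed the test (adjusted p = 0.0033). That mean includes 1 probe set of low signal that was not tested alone (16.5 in Control and 2.9 in 7-OHMTX).

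Among the 9 measured genes of folate transport and polyglutamylation, 3 rose and 4 fell (camera, adjusted p = 0.941). Besides GGH, the drug exporter ABCC4 rose from 33.4 ± 5.95 to 128 ± 21, and the mitochondrial folate carrier SLC25A32 from 184 ± 7.61 to 390 ± 104. Besides FPGS, the folate receptor FOLR1 fell from 203 ± 38.5 to 72.7 ± 24.8 in 1 probe set, while its other tested probe set did not pass. ABCG2 fell from 50.4 ± 2.62 to 18.9 ± 15.1. ABCC1 fell from 225 ± 0.30 to 159 ± 26.6 (adjusted p = 0.0418), and without 7-OHMTX replicate 1 or 3, or Control replicate 1, 2 or 3, its adjusted p was 0.0689, 0.165, 0.0929, 0.0935 or 0.097, with changes of -0.52 to -0.34 compared with -0.47 from all arrays. It was also over the threshold with no filter (0.0694) and with a replicate block (0.0604), while its other tested probe set fell by 0.74 (adjusted p = 0.00481). Of the 15 one-carbon enzymes, 6 rose and 3 fell (camera, adjusted p = 0.9). The glycine cleavage enzyme GLDC fell from 92.6 ± 4.84 to 9.62 ± 4.15, while its partner GCSH rose from 309 ± 9.05 to 657 ± 68.4. The mitochondrial enzymes MTHFD2 and MTHFD2L rose by a log2 of 0.78 and 1.25. The purine synthesis enzyme GART fell from 361 ± 8.89 to 241 ± 20.6 (adjusted p = 0.0136). GART did not pass with the mean of its probe sets (adjusted p = 0.0734) or without 7-OHMTX replicate 3 (a change of -0.50, adjusted p = 0.0522). Of its other tested probe sets, 1 fell by 0.94 (adjusted p = 0.000157), 1 rose by 0.72 (adjusted p = 0.00244) and 1 changed by -0.06 (adjusted p = 0.824). Smaller rises in DLD, MTHFD1 and QDPR, of 0.47, 0.47 and 0.41, lay near the threshold and missed it in several settings with fewer arrays, where the changes were 0.39 to 0.45, 0.41 to 0.51 and 0.32 to 0.42. DLD did not pass without 7-OHMTX replicate 3 or Control replicate 1 or 2 (adjusted p = 0.0687, 0.0521 and 0.0651), and MTHFD1 without any 1 array of these 2 groups (0.0708 to 0.146) or in 6 other settings (0.0515 to 0.0991). QDPR did not pass without 7-OHMTX replicate 1 or 3 or any Control replicate (0.0907 to 0.151) or in 5 other settings (0.0535 to 0.167).

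In limma's moderated test 5545 of 12297 probe sets (45.1%) changed between the arrays labelled 7-OHMTX and Control, 2685 up and 2860 down. By the probe set with the highest mean of each gene, 3340 genes changed, and 1626 of the 5545 probe sets changed at least 2-fold. Groups of arrays did not overlap for 58.6% of tested probe sets, where chance gives 10%. The Control arrays differ from all others in scaling target and in the ACTB ratio, so processing and group coincide in this comparison. Against the MTX arrays, which share the scaling target of 7-OHMTX, the median of the T lineage list was -0.94. In 8.23% of the 826 genes with several changed probe sets, these went in opposite directions.

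**Figure D1:**
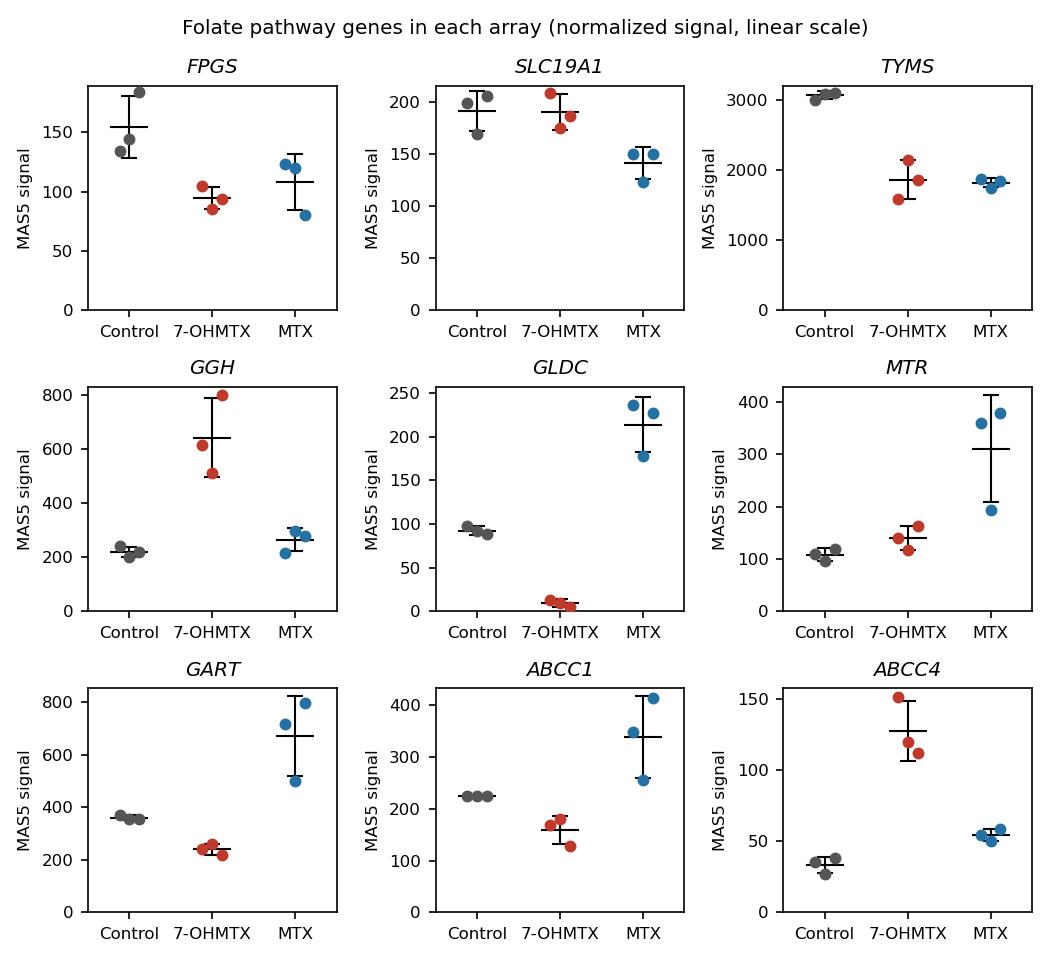
Normalized array signal (linear scale, from 0) of 9 folate genes in Control, 7-OHMTX and MTX arrays. Points are single arrays and bars the mean ± SD (n = 3); GGH was at 641 in the arrays labelled 7-OHMTX and 220 in Control, and GLDC was at 9.62 and 92.6.

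The comparison of MTX with Control asked what differs in the subline selected on the parent drug. DNTT, the template-independent DNA polymerase of immature lymphocytes, rose from 3.85 ± 0.71 to 123 ± 7.98 (SD, n = 3), and TRIM22, an interferon-induced antiviral protein, from 11.2 ± 4.01 to 158 ± 2.89. ID1, an inhibitor of basic helix-loop-helix factors, rose from 17.3 ± 1.76 to 138 ± 28.1, and the integrin ITGA4 from 349 ± 21.7 to 1212 ± 387. The stress transcription factor ATF5 fell from 470 ± 49.1 to 41.8 ± 10.6. IGFBP2, which binds insulin-like growth factors, fell from 1166 ± 41.4 to 150 ± 12.2.

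The other named rises were in TASOR2, ATP13A3, ATP11B, SLC4A7, DDX60 and TRAPPC11, with log2 changes of 1.60 to 1.91. ZNF580, DDIT4, FADS2, SF3A2, CD9, EMP3, PHC1 and PRKCH had changes of -2.95 to -2.08. Each of these genes had an adjusted p of 0.000536 or lower.

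Camera called 7 of 35 lists lower in the MTX arrays, and 3 higher. For comparison with the member counts below, 1278 of all 7448 tested genes rose and 1395 fell. With an estimated correlation camera called 0 lists (8 at an unadjusted p under 0.05), and fry called 21. Of 22 measured genes of cholesterol synthesis 17 fell and 0 rose, and adjusted over the list alone 19 fell (median -0.77; camera, adjusted p = 7.18e-09; adjusted p = 0.192 with an estimated correlation). INSIG1, a sterol sensor, fell by a log2 of 1.68, and DHCR7, the last enzyme of the pathway, from 310 ± 31.0 to 90.5 ± 5.62. In glycolysis and hypoxia 20 of 31 fell and 2 rose, adjusted over the list alone 21 and 2 (median -0.66; adjusted p = 4.97e-07; adjusted p = 0.192 with an estimated correlation). The glycolytic enzymes ALDOC and GPI fell from 237 ± 15.5 to 45.5 ± 9.71 and from 1517 ± 24.4 to 428 ± 8.13. In the NRF2 and oxidative stress list 14 of 29 fell and 1 rose, adjusted over the list alone 15 and 1 (adjusted p = 0.00593; adjusted p = 0.622 with an estimated correlation). Of these, the metallothioneins MT1H, MT2A and MT1X changed by -1.48, -1.40 and -1.14. In oxidative phosphorylation 14 of 53 fell and 2 rose, also when adjusted over the list alone (adjusted p = 0.0302; adjusted p = 0.788 with an estimated correlation). This call ended without Control replicate 1 (adjusted p = 0.0841) or MTX replicate 1 (0.787), with median centring (0.0736), without quantile normalization (0.0594) and with only the 2 groups compared (0.0559). ATP5F1D, a subunit of ATP synthase, fell by 1.75 and CYC1, of complex III, by 1.07.

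In serine synthesis and the amino acid stress response 14 of 29 fell and 2 rose, adjusted over the list alone 17 and 3 (median -0.39; adjusted p = 0.00156; adjusted p = 0.468 with an estimated correlation). Besides ATF5, the glutathione-degrading CHAC1 fell from 126 ± 60.5 to 26.1 ± 14.3 and the transcription factor CEBPB from 211 ± 28.6 to 56.6 ± 13.7. Of 17 NF-kB targets 10 fell and 1 rose, also when adjusted over the list alone (median -0.57; adjusted p = 0.00593; adjusted p = 0.192 with an estimated correlation). NFKBIA, the inhibitor of NF-kB, fell from 207 ± 28.7 to 45.8 ± 19.3, and the activation marker CD69 from 187 ± 12.8 to 102 ± 21.1. In actin cytoskeleton and adhesion 19 of 48 fell and 2 rose, adjusted over the list alone 20 and 2 (median -0.29; adjusted p = 0.00238; adjusted p = 0.211 with an estimated correlation). PFN1, which binds actin monomers, fell from 1884 ± 266 to 594 ± 225, while ITGA4 rose.

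Camera called 3 lists higher in the MTX arrays at the preset correlation, DNA repair, p53 targets and the 5q14 neighbourhood, and most members of the first 2 did not pass. In DNA repair 15 of 42 rose and 2 fell, also when adjusted over the list alone (median 0.28; camera, adjusted p = 0.0113; adjusted p = 0.192 with an estimated correlation). The helicase WRN rose from 65.1 ± 9.85 to 165 ± 37.6 and the checkpoint kinase ATR from 121 ± 4.59 to 280 ± 46.3. Of 19 p53 targets 7 rose and 0 fell, adjusted over the list alone 9 (median 0.39; adjusted p = 0.00593; adjusted p = 0.192 with an estimated correlation). GADD45A, a damage-induced growth arrest gene, rose from 34.9 ± 2.45 to 75.2 ± 9.03, and the phosphatase PPM1D from 136 ± 14.6 to 241 ± 37.7. The cell cycle inhibitor CDKN1A rose from 16.4 ± 14.4 to 40.0 ± 10.0 (adjusted p = 0.0294). It did not pass without Control replicate 1 or 2 or MTX replicate 1 or 3 (changes of 0.64 to 0.88, adjusted p = 0.132, 0.103, 0.103 and 0.0686) or with no filter (0.0836). Of 8 genes of the 5q14 neighbourhood 4 rose and 0 fell, also when adjusted over the list alone (median 0.40; adjusted p = 0.0167; adjusted p = 0.192 with an estimated correlation). The endosomal protein ZFYVE16 rose from 26.1 ± 0.82 to 102 ± 19.8 and the proteoglycan VCAN from 33.0 ± 1.20 to 77.6 ± 16. The other 2, MSH3 and SSBP2, rose by 0.61 and 0.43. Neither passed without Control replicate 2 (adjusted p = 0.06 and 0.104) or MTX replicate 3 (0.0627 and 0.0589), and SSBP2 also not without Control replicate 1 (0.0758) or 3 (0.144) or MTX replicate 2 (0.0979), or in 5 other settings (0.0512 to 0.177). With the values as deposited, the calls of DNA repair, p53 targets, the 5q14 neighbourhood, NF-kB targets, actin and oxidative phosphorylation ended (adjusted p = 0.642, 0.114, 0.125, 0.319, 0.102 and 0.246). In that setting the change of a gene also depends on its signal, through the added 16, so why these calls ended cannot be told.

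Changes in the MTX arrays went with gene length. Across 7447 genes, which are not independent replicates, the distance from start to end of the gene correlated with the change between MTX and Control at a Spearman's rho of 0.321. The value was -0.01 for 7-OHMTX against Control, -0.29 for 7-OHMTX against MTX, and 0.319 for MTX replicates 1 and 3 against MTX replicate 2. The T lineage list was not called in MTX against Control, with 9 genes up and 8 down of 39 (adjusted p = 0.52). Markers of other cell types were not called by camera either. The adjusted p was 0.52 for B cell genes (0 up, 0 down), 0.722 for myeloid (1 and 1), natural killer (0 and 0) and erythroid genes (1 and 0), and 0.86 for epithelial or fibroblast genes (1 and 2). Of these lists, fry called the B cell genes (adjusted p = 0.0185).

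Of 24 folate genes 8 rose and 5 fell between MTX and Control, and adjusted over the list alone 14 changed. The count of 13 went down to 6 without MTX replicate 3. TYMS fell from 3071 ± 57.2 to 1826 ± 69.1 (log2 change -0.75 ± 0.11 SE, adjusted p = 0.000337). FPGS fell to 108 ± 23.7 (-0.47 ± 0.17, adjusted p = 0.0468) by a margin that 11 alternatives removed. Its adjusted p was 0.0528, 0.0768 and 0.195 without Control replicate 1, 2 or 3, 0.213 without MTX replicate 3, and 0.0518 to 0.0926 in the other 7. The change was -0.34 without Control replicate 3 and -0.30 without MTX replicate 3. SLC19A1 fell to 141 ± 15.3 (-0.40 ± 0.14, adjusted p = 0.0432). It did not pass without Control replicate 1 or 3 or MTX replicate 1, 2 or 3 (changes of -0.44 to -0.32, adjusted p = 0.128, 0.152, 0.061, 0.0806 and 0.0652) or in 3 other settings (0.0509 to 0.0588). Its other tested probe sets fell by 1.35 and 1.0 (adjusted p = 0.000221 and 0.0019). GGH was at 265 ± 42.4 (0.24 ± 0.18, adjusted p = 0.305).

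Of the 9 folate transport genes 4 rose and 3 fell (camera, adjusted p = 0.585), and of the 15 one-carbon enzymes 4 rose and 2 fell (adjusted p = 0.326). GLDC rose from 92.6 ± 4.84 to 214 ± 31.3, GART from 361 ± 8.89 to 672 ± 153 and MTR, methionine synthase, from 109 ± 11.6 to 311 ± 102. MTX replicate 2 was the lowest MTX array for each, at 178, 502 and 193, though above every Control array. FOLR1 fell to 60.6 ± 22.5 in the same probe set, and SHMT2, the mitochondrial serine hydroxymethyltransferase, from 739 ± 29.7 to 492 ± 26.5. Other tested probe sets of GART rose too, by 0.52 to 1.16, while those of SHMT2 changed by -0.25 and -0.41 (adjusted p = 0.204 and 0.0526). The exporters ABCC1, ABCC4 and ABCC5 rose by 0.53, 0.52 and 0.59, and SLC25A32 and DLD by 0.49 and 0.45. These calls lay near the threshold and missed it in several settings with fewer arrays. The changes there were 0.38 to 0.53 for ABCC1, 0.42 to 0.48 for ABCC4, 0.48 to 0.58 for ABCC5, 0.46 to 0.52 for SLC25A32 and 0.33 to 0.47 for DLD. ABCC1 did not pass without Control replicate 1, 2 or 3 or MTX replicate 1 or 3 (0.0755 to 0.143), with no filter (0.0584), as deposited (0.109) or with the mean of its probe sets (0.162), and its other tested probe set changed by 0.11 (adjusted p = 0.686). For ABCC4 this held without Control replicate 2 (0.078) or MTX replicate 3 (0.0597), and for ABCC5 without Control replicate 1 (0.0589) or 3 (0.053) or MTX replicate 3 (0.0732). SLC25A32 did not pass without Control replicate 1, 2 or 3 or MTX replicate 1 or 3 (0.0716 to 0.108) or in 3 other settings (0.0668 to 0.133), nor DLD without Control replicate 1 or 2 or MTX replicate 1 or 3 (0.0564 to 0.0896) or as deposited (0.181).

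Between MTX and Control 4384 probe sets (35.7%) changed, 2231 up and 2153 down, and 807 changed at least 2-fold. By the probe set with the highest mean of each gene, 2673 genes changed. Arrays did not overlap for 48.4% of tested probe sets, where chance gives 10%. Changed probe sets of 1 gene went in opposite directions in 6.51% of 614 genes. Here too the scaling target and the ACTB ratio differ with the group.

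**Figure D2:**
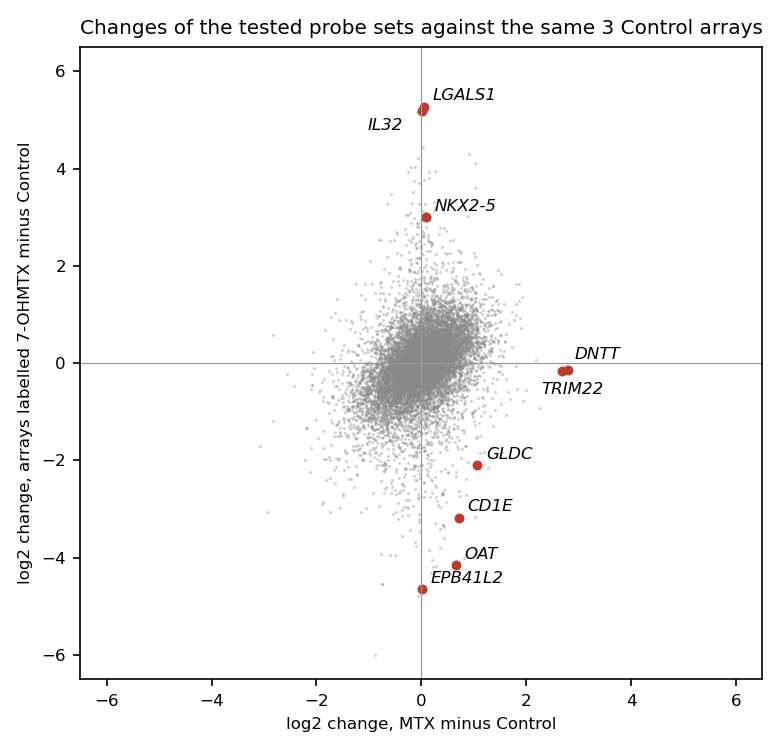
Log2 change of each tested probe set in MTX minus Control (x axis) and in the arrays labelled 7-OHMTX minus Control (y axis). Named genes are in red; LGALS1 had a y value of 5.27 and DNTT an x value of 2.80.

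The 2 sublines shared the same 3 Control arrays, which alone makes their changes alike. The changes correlated across probe sets at 0.355, below the 0.50 of 200 simulations with no effect of selection (0.473 to 0.522), while the covariance was 0.145 compared with 0.0162 in the simulations. Probe sets higher in both numbered 974 (487 if the calls were independent), lower in both 1124 (501), and 374 were called in opposite directions. Shared controls also raise such overlaps, and the share of all tested probe sets with the same sign in both was 66.4%, compared with 66.7% in the simulations. The simulations hold noise only, so these like shares do not show that shared controls account for the overlaps. Part of the excess in the overlaps may come from the shared controls, and 3 Control arrays cannot be split into separate sets of at least 2. The Control arrays also differ from both sublines in scaling target and ACTB ratio, and the simulations hold no such difference. Changes shared by both sublines, and the higher covariance, therefore cannot be told apart from a processing difference of the Control arrays.

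Compared directly, the arrays labelled 7-OHMTX and the MTX arrays, which share a scaling target, differed in 9 of 35 lists by camera at the preset correlation, 6 higher and 3 lower in 7-OHMTX, and in 1 with an estimated correlation. ASNS, asparagine synthetase, was at 1174 ± 70.4 in 7-OHMTX and 56.5 ± 7.14 in MTX (SD, n = 3; Control 92.8 ± 22.6), and LZTFL1 was at 14.2 ± 1.34 and 537 ± 76.0. SOSTDC1, LGALS1, IL32, VAMP8, CYTL1, SSX1, CRIP1, IFITM2 and TENT5A were higher in 7-OHMTX by 3.39 to 5.24. BEX3, OAT, EPB41L2, CCR9, CERS6, BEX1 and TCEAL9 had changes of -5.11 to -4.26. Among all 7448 tested genes 1547 were higher and 1592 lower in 7-OHMTX.

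In serine synthesis and the amino acid stress response 19 of 29 genes were higher in 7-OHMTX and 2 lower, also when adjusted over the list alone (median 0.84; camera, adjusted p = 1.61e-06; adjusted p = 0.265 with an estimated correlation). PSAT1, of serine synthesis, was at 1598 ± 134 and 331 ± 41.7, and CEBPB at 448 ± 24.8 and 56.6 ± 13.7. For cholesterol synthesis 15 of 22 were higher and 0 lower, adjusted over the list alone 17 and 0 (median 0.90; adjusted p = 1.56e-06; adjusted p = 0.265 with an estimated correlation), including MSMO1 at 1139 ± 189 and 213 ± 19.0. For glycolysis and hypoxia 19 of 31 were higher and 1 lower, also when adjusted over the list alone (median 0.73; adjusted p = 1.35e-05; adjusted p = 0.265 with an estimated correlation), including the hypoxia-induced BNIP3 at 356 ± 31.3 and 43.1 ± 8.40. In oxidative phosphorylation 25 of 53 were higher and 1 lower, adjusted over the list alone 27 and 1 (adjusted p = 5.03e-05; adjusted p = 0.647 with an estimated correlation). CYC1 was at 983 ± 105 and 257 ± 115. Against Control, cholesterol synthesis and glycolysis and hypoxia were not called in 7-OHMTX, with medians of -0.06 and -0.05 (camera, adjusted p = 0.941 each). In MTX against Control their medians were -0.77 and -0.66. For oxidative phosphorylation the medians against Control were 0.20 in 7-OHMTX and -0.27 in MTX. The differences between the sublines use the same MTX arrays as these falls. In the NRF2 and oxidative stress list 17 of 29 were higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.00146; adjusted p = 0.517 with an estimated correlation), with the metallothioneins MT1X, MT1E, MT1F and MT2A higher by 1.67 to 2.19. Of 50 cytosolic ribosomal proteins 14 were higher and 1 lower, adjusted over the list alone 11 and 1 (adjusted p = 0.0346; adjusted p = 0.751 with an estimated correlation). This call ended without MTX replicate 1 (adjusted p = 0.182) and with the mean of each gene's probe sets (0.0557), and RPL36, RPL35A, RPL35 and RPL8 were higher by 1.10, 0.75, 0.64 and 0.61. RPL35A did not pass with the mean of its probe sets (0.23, adjusted p = 0.236). RPL35 did not pass without MTX replicate 1 (0.31, adjusted p = 0.0744), without 7-OHMTX replicate 2 (0.63, adjusted p = 0.073) or 3 (0.61, adjusted p = 0.0771), or with no filter (adjusted p = 0.0915).

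T lineage genes were lower in the arrays labelled 7-OHMTX than in the MTX arrays in 29 of 39 cases and higher in 4, adjusted over the list alone 30 and 4 (median -0.94; camera, adjusted p = 3.48e-10; adjusted p = 0.0186 with an estimated correlation). CD1C was at 2.82 ± 0.60 and 294 ± 48.9. In DNA repair 15 of 42 were lower and 4 higher, also when adjusted over the list alone (median -0.19; adjusted p = 0.0346; adjusted p = 0.265 with an estimated correlation), but not without 7-OHMTX replicate 2 (adjusted p = 0.054). The mismatch repair gene MSH3 was at 38.7 ± 5.26 and 127 ± 24.2, and the checkpoint kinase CHEK1 at 270 ± 46.0 and 654 ± 79.1. Of 8 genes of the 5q14 neighbourhood 4 were lower and 0 higher, also when adjusted over the list alone (median -0.59; adjusted p = 0.0473; adjusted p = 0.265 with an estimated correlation). This call ended without 7-OHMTX replicate 1 or 2 or MTX replicate 2 or 3 (adjusted p = 0.0565, 0.0775, 0.0628 and 0.0514), and in 4 other settings (0.0511 to 0.0683). SERINC5, a membrane protein, was at 204 ± 23.1 and 1008 ± 199. Lists of other cell types were not called by camera, with adjusted p of 0.66 for B cell (4 up, 2 down), 0.547 for myeloid (2 and 1), 0.457 for natural killer (1 and 1), and 0.904 for erythroid (0 and 1) and epithelial or fibroblast genes (1 and 1). Fry called the B cell, myeloid and natural killer lists (adjusted p = 0.0115, 0.0287 and 0.000895).

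The arrays labelled 7-OHMTX and the MTX arrays differed in 14 of 24 folate genes, with 9 higher and 5 lower in 7-OHMTX, and adjusted over the list alone in 15. FPGS differed by -0.15 (95% interval -0.51 to 0.22, adjusted p = 0.521) and TYMS by 0.02 (-0.22 to 0.27, adjusted p = 0.885). FOLR1 differed by 0.22 (-0.30 to 0.74), DLD by 0.02 (-0.29 to 0.32) and MTHFD1 by 0.01 (-0.38 to 0.39). GGH was higher in 7-OHMTX by 1.21 (0.84 to 1.59, adjusted p = 8.62e-05), ABCC4 by 1.02 (0.69 to 1.35, adjusted p = 0.000108) and GCSH by 0.92 (0.59 to 1.26, adjusted p = 0.000321). SHMT2, MTHFD2L and MTHFD2 were higher by 0.64, 0.82 and 0.53, while the other tested probe sets of SHMT2 differed by 0.59 (adjusted p = 0.00721) and 0.03 (adjusted p = 0.883). GLDC differed by -3.17 (-3.51 to -2.83, adjusted p = 1.88e-09), GART by -1.40 (-1.75 to -1.04), ABCG2 by -1.62 (-2.16 to -1.07), MTR by -1.03 (-1.49 to -0.56) and ABCC1 by -1.01 (-1.39 to -0.63). The other tested probe set of ABCC1 differed by -0.84 (adjusted p = 0.00212), and those of GART by -1.55, -1.22 and 0.20, the last with an adjusted p of 0.341.

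Small differences in SLC19A1, SLC25A32 and QDPR lay near the threshold and missed it in several settings with fewer arrays, where they were 0.31 to 0.44, 0.32 to 0.50 and 0.35 to 0.40. SLC19A1 was higher in 7-OHMTX by 0.39 (0.08 to 0.70, adjusted p = 0.0408), but did not pass without 7-OHMTX replicate 1 or 3 or MTX replicate 1, 2 or 3 (adjusted p = 0.143, 0.0663, 0.0533, 0.0816 and 0.0588) or in 5 other settings (0.0579 to 0.0786). Its other tested probe sets differed by -0.01 (adjusted p = 0.974) and 0.80 (adjusted p = 0.00497). SLC25A32 was higher by 0.49 (0.32 without 7-OHMTX replicate 1), but did not pass without 7-OHMTX or MTX replicate 1 or 3 (0.0705 to 0.176), with no filter (0.0558) or with only the 2 groups compared (0.0688). QDPR was higher by 0.43, but did not pass without these same arrays (0.113 to 0.125), with only the 2 groups compared (0.0836) or with a replicate block (0.0598). Of the folate transport genes 4 were higher and 2 lower (camera, adjusted p = 0.851). Of the one-carbon enzymes 5 were higher and 3 lower (adjusted p = 0.904), with a median of 0.02, a mean of -0.12 and a test direction of higher.

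Between the 2 sublines 5134 probe sets (41.8%) differed, 2479 higher and 2655 lower in the arrays labelled 7-OHMTX, and 1570 differed at least 2-fold. By the probe set with the highest mean of each gene, 3139 genes differed. Arrays did not overlap for 47.6% of tested probe sets, where chance gives 10%. Changed probe sets of 1 gene went in opposite directions in 3.06% of 785 genes. Each drug was used in 1 selection and at its own dose, so differences between sublines are not differences between drugs at matched dose. RNA of another cell line or a wrong label in the arrays labelled 7-OHMTX also stays open for these differences.

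**Figure D3:**
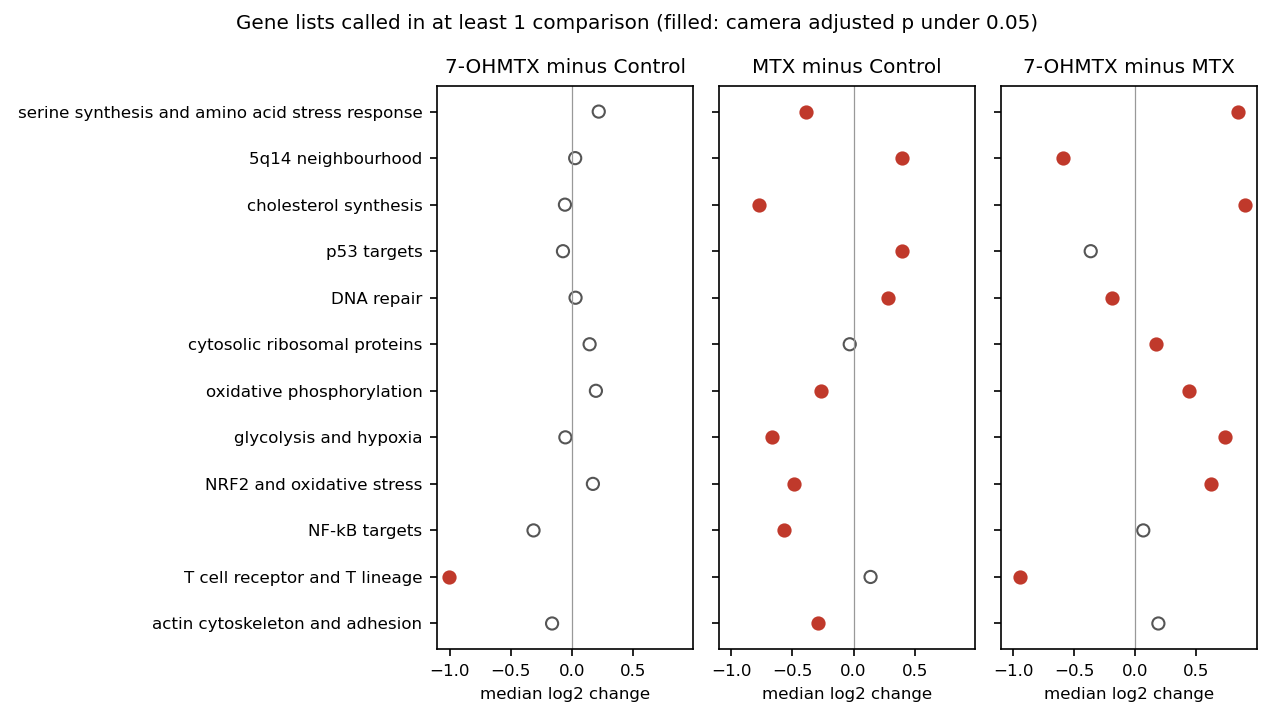
Median log2 change of the measured genes of 12 lists, those called in at least 1 comparison, in 1 panel per comparison (x axis, log2). Filled points have a camera adjusted p under 0.05 and open points do not; T lineage genes had medians of -1.01 (7-OHMTX minus Control), 0.14 (MTX minus Control) and -0.94 (7-OHMTX minus MTX).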

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

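Tests of gene span and of other splits of the arrays were planned, and the other tests here were chosen only after the results were seen. The difference between the arrays labelled 7-OHMTX and the MTX arrays was tested for 3 folate genes picked because they changed in opposite directions from Control, which fixes the sign of that difference. ABCC1 differed by -1.01, GLDC by -3.17 and GART by -1.40 on the log2 scale. With some arrays left out, the changes from Control missed the threshold for ABCC1 in both sublines and for GART in 7-OHMTX. Their sizes were then -0.52 to -0.34 and 0.38 to 0.53 for ABCC1, and -0.50 for GART. A second probe set of ABCC1 fell by 0.74 in 7-OHMTX (adjusted p = 0.00481) and changed by 0.11 in MTX (adjusted p = 0.686). Among control probe sets for 18S ribosomal RNA, outside the gene comparisons, some lay above every Control array in all 3 arrays of a subline. For the 3' probe set this held in both sublines, with means of 1745 in 7-OHMTX and 1780 in MTX (Control 363). For the 5' and middle probe sets it held in MTX, with means of 719 and 562.

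The arrays labelled 7-OHMTX stand apart: outside the X and Y chromosomes, 49 genes on 19 chromosomes were at 100 or more in all 3 and under 20 in the 6 others, or the reverse, compared with 2 for MTX. A separate scaling or scan of the Control arrays is argued against for this pattern, because the lowest correlation of a Control with an MTX array was 0.900 and the highest of a 7-OHMTX with an MTX array 0.879. RNA of another cell line or a wrong label stays open, and the 49 genes are consistent with it. Selection on the drug stays open too: that 8.16% of these genes changed the same way in MTX against Control carries no weight, since the rule that picked them places the MTX arrays with Control. No genotype was used here, so these explanations were not separated.

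The MTX changes follow gene length, with a Spearman's rho of 0.321 between gene span and the change from Control. A length-dependent difference in RNA or labelling may therefore contribute to the lists and single genes that moved. Within MTX, replicates 1 and 3 minus replicate 2 correlated at 0.383 with the change from Control, so a gradient among these arrays may contribute as well; the same value was -0.324 for replicate 1, -0.171 for replicate 3, and -0.0888 to 0.0790 for the arrays of the other groups with the changes from Control. Of the 145 changed genes in the 10 lists called, 91 (62.8%) also differed, in the same direction, between the MTX and the 7-OHMTX arrays with their shared scaling target. Over all 2673 genes changed between MTX and Control, this held for 1113 (41.6%). Both comparisons use the same MTX arrays, and the arrays labelled 7-OHMTX stand apart from both other groups. These shares therefore cannot decide whether a scan or scaling batch of the Control arrays is the cause. Such a batch cannot be told apart from selection, since the scaling target and the group coincide. For Control against the 6 others, the exact permutation p was 0.0119 for the ACTB ratio (0.178 after adjustment over 16 tests). It was 0.619 for the GAPDH ratio. Selection on MTX stays open and was not tested apart from these.

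Among 100 splits of the 9 arrays into 3 groups of 3, only the real one reached 7560 probe sets by the F test, and the highest other gave 2662. This argues against a random grouping of the arrays for this count. It does not bear on the cause, since each subline comes from 1 selection and the Control arrays have their own scaling target. For each pair of groups 10 splits are too few for a share under 0.05, and 1 of 10, the real one, reached the count of changed probe sets. The real counts were 5545, 4384 and 5134 for 7-OHMTX against Control, MTX against Control and 7-OHMTX against MTX. The highest other by limma was 0 each, with 255, 1213 and 1176 at an unadjusted p under 0.05. Real counts of folate genes were 16, 13 and 14, and the highest other by limma was 0 each, with 1, 2 and 3 at an unadjusted p under 0.05. For lists called by camera the real counts were 1, 10 and 9 and the highest others 3, 8 and 7. For 7-OHMTX against Control, 10 of 10 splits called as many lists. Every other split of a pair places arrays of both groups on each side. The group difference then enters the spread and partly remains between the sides. Counts from these splits are therefore not those of unchanged groups.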

How the results depend on the processing

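The ordinary test, median centring, fry, an estimated correlation and leaving out arrays were planned, and 2 settings were chosen after seeing the data: a common trimmed mean without quantile normalization and one of 500 with it. The cause was not tested for the values below, except where fewer arrays or degrees of freedom limit the test. No named gene reversed, and of 201 results for named genes 188 to 200 kept their side of the threshold in settings with all arrays. The deposited values shift the median log2 change by -2.13 (7-OHMTX minus Control), -2.10 (MTX minus Control) and -0.01 (7-OHMTX minus MTX). They call 12091 probe sets, with 1.03% of them higher, 12189, with 0.0328% higher, and 12269 by the F test. Named-gene changes were taken relative to that shift; without this the sign differs for 9 of 38 and 27 of 69 called genes in the 2 comparisons with Control. Genes of low signal shift less than the median in these comparisons, because the Control values are 5 times larger beside the added 16. List calls as deposited therefore cannot decide there whether a list changed. The ordinary test called 2018 probe sets for MTX minus Control and 2584 for 7-OHMTX minus MTX, and 6 folate genes in each. At least 2-fold changes numbered 1626, 807 and 1570. The deposited values called 24 folate genes for MTX minus Control, and leaving out 1 array gave 6 to 14. Leaving out 1 array gave 4408 to 4769, 3104 to 5240 and 3993 to 5828 changed probe sets. Lists called for 7-OHMTX minus Control numbered 3 without quantile normalization, 2 with median centring, 6 as deposited, 15 by fry and 1 to 2 with 1 array left out. For MTX minus Control they were 0 by camera with an estimated correlation (8 at an unadjusted p under 0.05) and 21 by fry, and for 7-OHMTX minus MTX 1 and 23. The direction reversed for actin in 7-OHMTX minus Control (adjusted p 0.0213 by fry, 0.00758 as deposited), early progenitor genes in 7-OHMTX minus MTX (0.0488 by fry) and mitosis in MTX minus Control (0.0363 as deposited). The correlation of the sublines' changes was 0.323 with array weights, 0.329 with a trimmed mean of 500, 0.316 with 1 added, 0.510 as deposited, and 0.327 to 0.408 with 1 array left out. Replicate numbers do not pair the arrays (correlations of deviations -0.123 to 0.0601), and a replicate block called 5420, 4237 and 5036 probe sets. Signal near background limits low genes, since adding 16 understates their change.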

Other observations

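The on or off genes named here, and the test that found them, were chosen only after their values were seen. Among the genes at 100 or more in the arrays labelled 7-OHMTX and under 20 elsewhere, NKX2-5, a homeobox factor, was at 162 ± 55.9 in 7-OHMTX (SD, n = 3), 5.46 in Control and 7.13 in MTX. MEF2C was at 172, 7.45 and 10.8 in the same order. MEIS2 and PROCR, the endothelial protein C receptor, were at 156 and 157 in 7-OHMTX and 15.6 and 6.18 in Control. NCF4, a subunit of the phagocyte oxidase, was at 132 and 1.53. Of the interferon response list, 13 of 34 measured genes rose and 8 fell in 7-OHMTX against Control (camera, adjusted p = 0.712), and the list was called higher as deposited (adjusted p = 0.000554) and by fry (0.0358). As deposited, the added 16 alone ranks genes of low signal higher, so that call cannot decide whether the list rose.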
